A study of Arabidopsis thaliana with 8 samples.

How the data were processed

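The study sequenced small RNAs from the aerial parts of 20-day-old Arabidopsis thaliana plants, grown for 6 days on MS medium and 14 days on soil. The labels give 8 libraries, 4 of es3 (ein5-1 ski2-3) and 4 of es3dd (es3 with the dcl4-2 and dcl2-1 mutations added), made with a small RNA library kit and read as single-end 50-bp reads. The submitters' processing notes name Bowtie 1.2.2, SAMtools 1.9, DESeq2 without a version and the build TAIR10, without saying what each tool was used for. The counting rules, the annotation and the treatment of reads that map to several places are not stated.

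The deposited file holds 32420 genes, with group means in place of libraries. Its mean columns are in the authors' TPM, here read counts brought to a common total and not divided by gene length, with the 21-nt and 22-nt classes scaled apart. The denominator of that TPM is not stated by the authors. The authors also give a log2 fold change for es3 over Col and for es3 over es3dd in each size class. The authors' p-value and adjusted p-value stand beside each fold change. Col is the wild type, which appears in the deposited file but not among the labelled libraries of this series. Its values were therefore used only as the authors' means and comparisons. Other per-sample columns not used numbered 0.

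The value of each library was recovered from the group means. Low means in each column were sums of whole multiples of 4 steps, where a step is the share that 1 read of 1 library adds to the mean. Each mean of up to 1500 reads over the 4 libraries was matched to whole reads per library at a relative tolerance of 5e-15. For es3, 25227 of 25227 genes tried at 21 nt and 23743 of 23743 at 22 nt had a single match. For es3dd, 21557 of 21557 and 21836 of 21836 did, and 0 of as many random values matched in any column. Genes above that reach numbered 162 and 67 in es3 and 83 and 47 in es3dd, at 21 and 22 nt. In simulated means, 99.98% (es3, 21 nt) or 100% (the other columns) were recovered exactly and 0 were wrong. The decoded genes held 35.3% of the summed 21-nt signal and 71.1% of the 22-nt signal in es3, and 14.4% and 63.8% in es3dd. Genes above reach were not tested here and are described from the authors' deposited table. The recovery, limma on the recovered values, scaling to MIR loci and to plastid-encoded genes, the voom weights, the read scale of both size classes, camera on ranks of the authors' p-values and the minimum of 10 in the authors' table were decided after the file had been seen. A planned replicate block, a paired ratio within libraries, the top 10 genes of each library and totals leaving libraries out were planned but not run, since the recovered libraries lack replicate numbers and the most abundant genes were not recovered. Planned count-based tools were not run either, and limma with voom weights on the recovered whole reads was fitted in their place.

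Gene-wise tests used limma 3.58.1 in R 4.3.3, with its mean-variance trend, on log2(value + 1). Genes with a mean of at least 1 over the libraries of a test were kept. A gene was called at an adjusted p below 0.05 (Benjamini-Hochberg over all genes kept) and an absolute log2 difference of at least 1. Values are means ± SD over the 4 recovered libraries, and log2 differences carry their SE. A group at 0 reads was given a floor of 3 reads over the group for a lower bound on the fold, which covers counting error only. For genes above reach in es3, the same floor or, at 1 to 3 reads in es3dd, the 95% exact Poisson interval of that count was set against the authors' es3 mean, a step chosen after the results had been seen. In each comparison, the gene lists with at least 2 recovered members above the filter were tested with limma's camera at an inter-gene correlation of 0.01 and again with an estimated correlation, with adjustment over the lists tested. TAS loci had no row and were not tested. On recovered values the 22-nt siRNA genes of the study were tested only within es3dd, and the PPR genes only at 22 nt and within es3dd. The 18 lists were trans-acting siRNA (TAS) loci, tasiRNA target ARF genes, the 22-nt siRNA genes of the study, RNA silencing factors, cytoplasmic RNA decay factors, miRNA target transcripts, PPR genes of the phased siRNA cluster, NLR genes of the miR472 family, nitrogen genes, the SMAX1-LIKE family, nuclear photosynthesis genes, ABA, cold and drought genes, housekeeping genes, root-specific genes, plastid-encoded genes, mitochondrion-encoded genes, MIR loci and transposable element genes. The transposable element list holds only the 88 loci whose annotation note or product names a transposon, and it may miss other transposable element genes. The lists, the thresholds, limma with a trend for values of this unit, camera and the other alternatives were fixed before the data were examined, for deposited library columns in place of recovered ones.

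No paired analysis was possible because the recovered libraries carry no replicate numbers, so that a 21-nt library cannot be matched to the 22-nt library of the same plants. Comparisons of 22-nt with 21-nt values therefore ran with no replicate block, with the columns of the size classes as independent groups, and gave 2314 genes higher and 4908 lower at 22 nt in es3 and 767 higher and 170 lower in es3dd.

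Genes named in the text follow a rule fixed in advance. It takes, per comparison, up to 10 called genes with the largest and up to 10 with the smallest difference whose libraries all lie on that side. It adds up to 10 genes with the highest es3 mean per size class, the 4 mutated genes, the study's own 22-nt siRNA genes and up to 4 members of each other list with the highest es3 mean. Fewer are named where space asks for it, always from the top. AT2G01021 and AGO2 were also singled out after their values had been seen. Positions are those of the TAIR10.1 reference annotation, which may differ from the build the authors used, and 31722 of the 32420 identifiers matched it.

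Simulated genes gave a guide to what the tests could find, with 200 genes raised per test and read counts drawn with an assumed negative binomial size of 10. With 50 changed genes per fold, the 21-nt test called 6%, 76%, 98% and 100% at 2, 4, 8 and 16-fold, and the 22-nt test 6%, 54%, 98% and 100%. The 22-nt against 21-nt test called 2%, 58%, 88% and 100% in es3 and 2%, 54%, 90% and 100% in es3dd. The test of the difference between these ratios called 2%, 10%, 46% and 82%. False calls ranged from 0.01% to 0.05% of unchanged genes. Far more genes were called in the real data than were changed here, and the spread was not estimated from the data. A 2-fold change also tends to miss the log2 threshold once the pseudocount is added. These rates therefore may not carry over to the real tests.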

Results

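Small RNAs of 21 and 22 nt were measured per gene in plants lacking both arms of cytoplasmic RNA decay. In es3, the 5'-3' exoribonuclease EIN5 (XRN4) and the exosome helicase SKI2 are mutated. In es3dd, the Dicer enzymes DCL4 and DCL2, which make 21-nt and 22-nt siRNAs, are mutated as well. Each genotype had 4 libraries. The recovered scale of a library, the number of reads that its values were divided by, ran from 1.219 to 1.442 for es3 at 21 nt and from 1.057 to 1.319 at 22 nt, in units of 1e6 reads. For es3dd it ran from 1.035 to 1.129 and from 1.125 to 1.243. A value of 1 therefore rests on 1 or 2 reads in a library, and counting error alone is large at that level.

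MIR loci, which encode microRNA precursors, and other genes shared the 21-nt signal very differently in the 3 genotypes. The authors' mean columns gave MIR loci 68.4% of the summed 21-nt signal in Col, 33.2% in es3 and 83% in es3dd. Other nuclear genes held 27.2% in Col, 65.6% in es3 and 15% in es3dd. At 22 nt, MIR loci held 15.2%, 8.2% and 28.4%, and plastid-encoded genes 10.1%, 3% and 6.9%. The authors' means summed to 608436, 525481 and 757782 at 21 nt and to 236507, 225727 and 215894 at 22 nt, for Col, es3 and es3dd. Sums per library could not be formed because the genes above reach hold much of the signal, so these totals and shares carry no spread and were not tested.

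**Figure D1:**
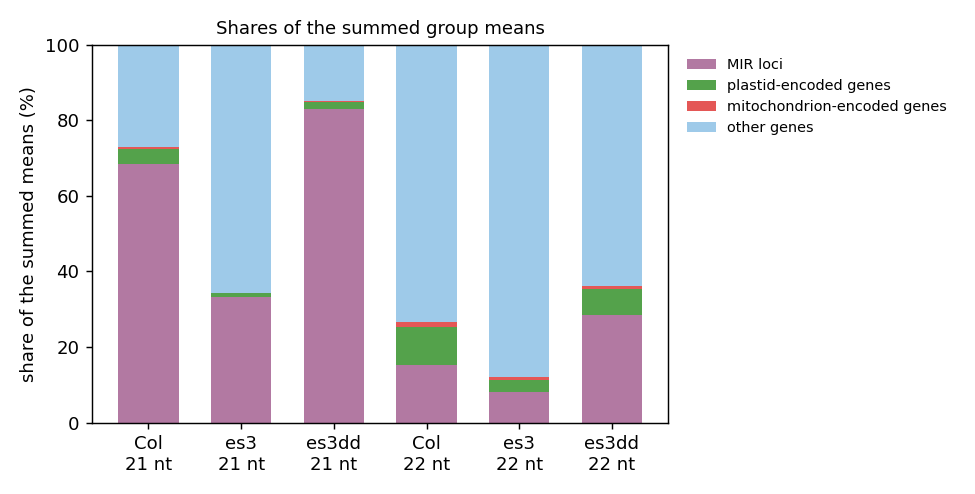
Stacked bars give the share (%) of the authors' summed group means that came from MIR loci, plastid-encoded genes, mitochondrion-encoded genes and other genes, for each genotype and size class. MIR loci held 33.2% of the 21-nt sum in es3 and 83% in es3dd, shares of means without a test.

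The 10 leading genes held 30.6% of the 21-nt sum of the authors' means in es3, against 62.7% in es3dd and 55.8% in Col. At 22 nt they held 11%, 21.6% and 24%. The 21-nt leader was MIR159a (AT1G73687, chromosome 1, 27713233 to 27713416) in es3, and MIR161 (AT1G48267, chromosome 1, 17825685 to 17825857) in es3dd. Outside MIR loci, the nitrate reductase gene NIA2 (AT1G37130, chromosome 1, 14158452 to 14161938) led the es3 21-nt class with 12110 as the authors' mean. The uncharacterized AT3G06435 (chromosome 3, 1968288 to 1970946) led the es3 22-nt class with 4487 as the authors' mean. Values of 10 or more in all 4 libraries were found for 3075 genes at 21 nt and 2600 at 22 nt in es3, and for 1766 and 2342 in es3dd. Genes above reach were counted among these.

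The comparison of es3 with es3dd asks which 21-nt siRNAs depend on DCL4 and DCL2. Transcripts of protein-coding genes carried far more of them in es3, where 7842 of 13378 tested rose and 290 fell, against 3240 and 1134 when median-centred and 12692 and 15 when scaled to MIR loci. PS2 (AT1G73010, chromosome 1, 27464528 to 27466348), an inorganic pyrophosphatase, stood at 256.8 ± 9.2 (SD, n = 4) in es3 and 0.46 ± 0.91 (SD, n = 4) in es3dd. Its log2 difference in limma was 7.63 ± 0.30 (SE), adjusted p = 8.8e-17. MIR loci moved the other way on the authors' scaling, with 63 of 84 lower and 2 higher, against 19 lower and 14 higher when scaled to plastid-encoded genes. In the authors' deposited table, which holds loci above reach too, 109 of 140 MIR loci were lower and 2 higher. In all, 7926 of 17301 tested genes rose and 1317 fell.

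The other large rises were at AT3G27250 (chromosome 3, 10061009 to 10062870, uncharacterized), which stood at 268.6 ± 30.6 in es3 and 0.72 ± 0.92 in es3dd (SD, n = 4). UF3GT (AT5G54060, chromosome 5, 21936746 to 21938396), a flavonoid glucosyltransferase, had a log2 difference of 6.90 ± 0.33 (SE). AT1G12300 (chromosome 1, 4183010 to 4186247), which encodes a repeat protein, rose from 0.69 ± 1.37 to 142.3 ± 15.6 (SD, n = 4). BLH1 (AT2G35940, chromosome 2, 15088762 to 15092415), a homeodomain factor, rose from 2.07 ± 1.35 to 267.5 ± 10.6 (SD, n = 4). The largest falls in limma among recovered genes were at AT2G14070 (chromosome 2, 5921881 to 5923151, wound-responsive protein-like), with 8.40 ± 3.05 in es3 and 272.8 ± 27.9 in es3dd (SD, n = 4), a log2 difference of -4.92 ± 0.20 (SE). MIR160b (AT4G17788, chromosome 4, 9888982 to 9889070) followed with -4.57 ± 0.53, MIR169e (AT1G53687, chromosome 1, 20041518 to 20041734) with -4.56 ± 0.25 and MIR844 (AT2G23347, chromosome 2, 9942151 to 9942335) with -3.96 ± 0.35 (SE). Their adjusted p in limma ran from 8.8e-17 to 6.8e-08, and these falls kept their direction under each scaling.

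Regulators of development and silencing were among the genes that gained 21-nt siRNAs. All 3 ARF genes that tasiRNAs target rose (3 of 3 adjusted over the list alone), by a median of 4.03, camera adjusted p = 0.00337 and adjusted p = 0.0509 with an estimated correlation. ARF2 (AT5G62000, chromosome 5, 24910191 to 24915395) rose by 4.03 ± 0.30, ARF3 (AT2G33860, chromosome 2, 14325206 to 14328978) by 2.99 ± 0.37 and ARF4 (AT5G60450, chromosome 5, 24308255 to 24312784) by 5.2 ± 0.39 log2 units (SE). Of 25 tested miRNA target transcripts 22 rose (22 adjusted over the list alone), median 3.6, adjusted p = 6.2e-10 and 0.00305 with an estimated correlation. Of 11 RNA silencing factors 9 rose (9 adjusted over the list alone), median 2.05, adjusted p = 0.00884, lost at adjusted p = 0.109 with an estimated correlation, and 5 rose under median-centring and under quantile normalization and 11 under scaling to MIR loci. AGO1 (AT1G48410, chromosome 1, 17885633 to 17892632), the main effector of microRNAs, stood at 252.3 ± 22.1 in es3 and 14.8 ± 6.5 in es3dd (SD, n = 4). DCL1 (AT1G01040, chromosome 1, 23121 to 31227), which makes microRNAs, stood at 74.1 ± 9.0 and 3.23 ± 1.15 (SD, n = 4). AGO7 (AT1G69440, chromosome 1, 26101407 to 26105328) rose by 3.44 ± 0.41 log2 units (SE). These 3 lists kept their direction under each scaling, as did the housekeeping list, whose median fell to 0.15 when median-centred.

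The lists of ABA, cold and drought genes, SMAX1-LIKE genes and NLR genes also lay higher, with camera calls that an estimated correlation removed. Of 10 ABA, cold and drought genes 9 rose (9 adjusted over the list alone), median 1.85, adjusted p = 5.7e-04 and 0.0581 with an estimated correlation, and 4 rose when median-centred, 5 after quantile normalization and 10 under scaling to MIR loci or plastid-encoded genes. The dehydrin gene ERD10 (AT1G20450, chromosome 1, 7087903 to 7089606) stood at 186.3 ± 34.9 in es3 and 9.02 ± 2.23 in es3dd, and ERD14 (AT1G76180, chromosome 1, 28586663 to 28587931) at 242.8 ± 12.2 and 16.2 ± 2.9 (SD, n = 4). All 5 tested members of the SMAX1-LIKE family, regulators of growth signalling, rose (5 adjusted over the list alone), median 2.64, adjusted p = 0.0101 and 0.059 with an estimated correlation, and 3 rose when median-centred or quantile-normalized, 4 under housekeeping scaling and 5 under scaling to MIR loci or plastid-encoded genes. SMAX1 (AT5G57710, chromosome 5, 23384255 to 23388465) stood at 63.7 ± 13 against 4.1 ± 2.5 (SD, n = 4). All 3 tested NLR genes of the miR472 family, which encode immune receptors, rose (3 adjusted over the list alone), median 3.06, adjusted p = 0.00884 and 0.059 with an estimated correlation. SCR (AT3G54220, chromosome 3, 20069987 to 20072878), the only gene tested of the list of root-specific genes, rose by 4.61 ± 0.32 log2 units (SE). Whether SCR is specific to roots was not tested, and the libraries came from aerial parts.

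Several lists moved less or not beyond the other genes. Of 10 nitrogen genes 6 rose (6 adjusted over the list alone), median 1.26, and camera made no call at adjusted p = 0.55, with 1 higher and 2 lower when median-centred and 9 higher and 0 lower under scaling to MIR loci or plastid-encoded genes. Of 6 RNA decay factors 3 rose (3 adjusted over the list alone), median 1.21, also at adjusted p = 0.55, with 1 higher under median-centring and quantile normalization and 6 under scaling to MIR loci or plastid-encoded genes. Of 11 housekeeping genes 6 rose (6 adjusted over the list alone), median 1.09, adjusted p = 0.0232 and 0.0673 with an estimated correlation, and 0 rose when median-centred, 1 after quantile normalization and 11 under scaling to MIR loci or plastid-encoded genes. UBQ10 (AT4G05320, chromosome 4, 2717977 to 2720308) stood at 128.2 ± 11.2 against 47.4 ± 2.1 (SD, n = 4). EF1A1 (AT1G07940, chromosome 1, 2462949 to 2465545) stood at 67.1 ± 5.7 against 40.6 ± 5.5 (SD, n = 4), a difference of 0.72 ± 0.16 (SE) that turned to -0.23 when the libraries were median-centred. Of 17 photosynthesis genes 0 rose and 1 fell by limma (0 and 1 adjusted over the list alone), median 0.00, below the other genes at adjusted p = 0.0318 and not at adjusted p = 0.387 with an estimated correlation. That median was -0.94, -0.53 and -0.40 under median-centring, quantile normalization and housekeeping scaling, and 1.60 and 1.57 under scaling to MIR loci and to plastid-encoded genes, where 16 were higher. RBCS1A (AT1G67090, chromosome 1, 25048158 to 25049667) stood at 245.1 ± 7.6 against 198.4 ± 19.1 (SD, n = 4), a difference that changed sign under median-centring and housekeeping scaling.

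Plastid-encoded genes and MIR loci fell in es3 on the authors' scaling. Of 79 plastid-encoded genes 68 fell and 0 rose (68 adjusted over the list alone), median -1.58, adjusted p = 6.4e-52 and 5.7e-04 with an estimated correlation. MIR loci fell by a median of -1.60 (64 lower and 3 higher adjusted over the list alone), adjusted p = 3.7e-42 and 9.975e-04 with an estimated correlation. Scaling to a list sets that list's own median to about 0. Under scaling to plastid-encoded genes the MIR median lay at -0.03, with 19 loci still lower and 14 higher, and under scaling to MIR loci the plastid median lay at 0.03, with 5 genes lower and 4 higher. Of 103 mitochondrion-encoded genes 15 fell and 1 rose (13 and 1 adjusted over the list alone), median -0.36, adjusted p = 1.3e-11 and 9.8e-04 with an estimated correlation, with 66 lower and 0 higher when median-centred, and the median turned to 1.25 and 1.21 (63 and 61 higher, 0 lower) under scaling to MIR loci and plastid-encoded genes. Of 60 transposable element genes 13 rose and 9 fell (12 and 8 adjusted over the list alone), median 0.03, below the other genes at adjusted p = 0.00884 and 0.0666 with an estimated correlation. That median was -0.91, -0.95 and -0.36 under median-centring, quantile normalization and housekeeping scaling (7 higher and 27 lower, the same counts, then 9 and 15). It was 1.64 and 1.60 under scaling to MIR loci and plastid-encoded genes, with 43 higher and 0 lower in both.

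The median of all genes tested at 21 nt lay 0.98 log2 units higher in es3, so that direction depends on the scale. The share of called genes that rose was 85.8% on the authors' scaling, 43% when median-centred (3272 higher, 4345 lower), 42.8% after quantile normalization (3243 and 4342), 68.6% with housekeeping and photosynthesis genes as the reference (5653 and 2591), and 99.7% with MIR loci (14374 and 43) or plastid-encoded genes (14242 and 47).

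**Figure D2:**
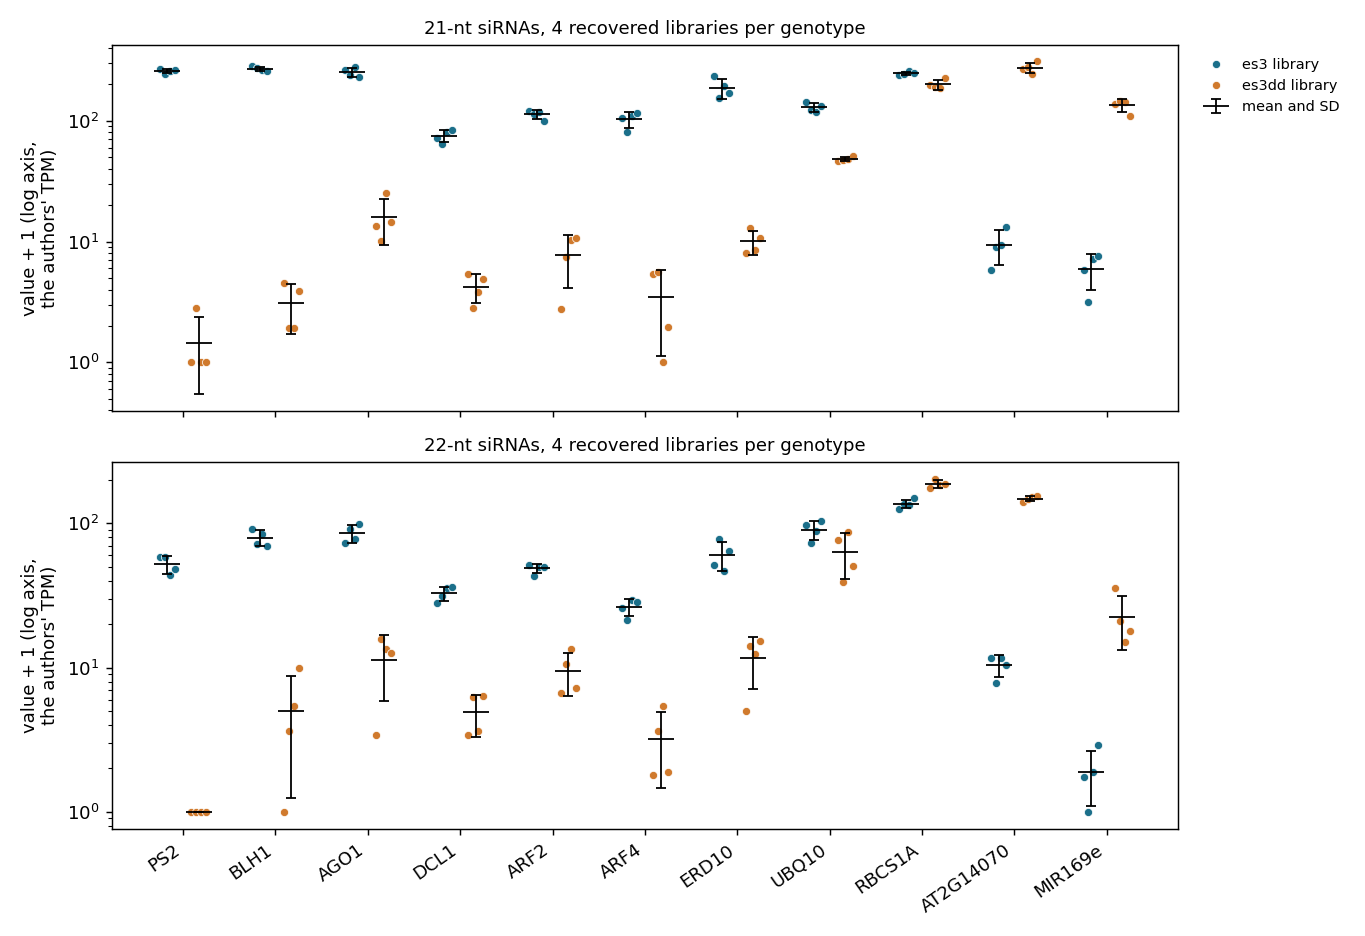
Points give the value + 1 of each of the 4 recovered libraries per genotype, in the authors' TPM on a log axis, for 11 named genes at 21 nt (upper panel) and 22 nt (lower panel), and bars give mean and SD. All es3 libraries of PS2, BLH1, AGO1, DCL1, ARF2, ARF4 and ERD10 lay above all es3dd libraries, the reverse held at AT2G14070 and MIR169e, and RBCS1A lay higher in es3 at 21 nt and lower at 22 nt, with directions that depend on the scaling.

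Genes too abundant to recover were compared in the authors' deposited table. The strongest 21-nt rises there were at pentatricopeptide repeat (PPR) genes of chromosome 1, a known source of phased siRNAs. The authors' deposited table gives AT1G62914 (chromosome 1, 23301315 to 23303162) a log2 fold change of 11.25 and AT1G63400 (chromosome 1, 23507178 to 23509484) 11.06. RPF2 (AT1G62670, chromosome 1, 23204256 to 23206822) had 752 as the authors' mean in es3 and 1 read in the 4 es3dd libraries, a ratio of 3114 (95% exact Poisson interval of that count 559 to 122987). All 10 PPR genes of that cluster were higher in es3 in the authors' deposited table (10 adjusted over the list alone). NIA2 had a log2 fold change of 8.83 and NIA1 (AT1G77760, chromosome 1, 29235721 to 29239484) 7.81 in the authors' deposited table. SMXL4 (AT4G29920, chromosome 4, 14632413 to 14636101) had 9.85 and SMXL5 (AT5G57130, chromosome 5, 23144947 to 23149615) 10.3 in the authors' deposited table. These last 4 genes were chosen by the study from such libraries, so their count (4 of 4 higher, 4 adjusted over the list alone) is not independent evidence of their direction. Falls at 21 nt among genes above reach included AT3G59240 with -4.92 and AT2G14090 with -4.59 in the authors' deposited table. Whether these loci share reads with AT2G14070 was not examined. Over 19089 genes the authors' deposited table has 6165 higher and 1261 lower at the same thresholds. Among 17237 genes tested in both, limma and the authors' deposited table shared 6008 rises and 1099 falls, and 0 genes were called in opposite directions. No row was analysed here for the 8 TAS loci.

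The 22-nt comparison asks the same of the class that the series title names. Genes higher in es3 were again mostly protein-coding, of which 2143 of 10438 tested rose and 196 fell, against 1203 and 522 when median-centred and 8381 and 11 when scaled to MIR loci. Of 3487 pseudogenes 39 rose and 277 fell, against 5 and 820 when median-centred and 1790 and 3 when scaled to MIR loci. FMO (AT1G12200, chromosome 1, 4137511 to 4140158), a flavin-binding monooxygenase gene, stood at 248.4 ± 8.5 in es3 and 0.22 ± 0.44 in es3dd (SD, n = 4), log2 difference 7.73 ± 0.28 (SE), adjusted p = 4.2e-43. The leaf polarity and vascular regulators REV (AT5G60690, chromosome 5, 24396981 to 24402195) and ATHB8 (AT4G32880, chromosome 4, 15863339 to 15868650), both targets of a microRNA, stood at 254.7 ± 24.4 and 266.2 ± 13.6 in es3 against 1.5 ± 1.1 and 1.53 ± 0.87 in es3dd (SD, n = 4). In all, 2200 of 14606 tested genes rose and 624 fell.

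WES1 (AT4G27260, chromosome 4, 13653579 to 13656285), an auxin-responsive GH3 gene, rose by 6.69 ± 0.30 and the PPR gene AT1G63150 (chromosome 1, 23419294 to 23421714) by 6.62 ± 0.27 log2 units (SE). PS2 had 0 reads in the 4 es3dd libraries and 51.3 ± 7.6 in es3 (SD, n = 4), at least 79.9-fold higher against a floor of 3 reads over the group. The largest falls were at MIR169i (AT3G26812, chromosome 3, 9871960 to 9872165), by -4.25 ± 0.31, AT3G59240 (chromosome 3, 21898682 to 21900364) by -3.95 ± 0.18 and the transcribed pseudogene AT2G14090 (chromosome 2, 5929814 to 5931809) by -3.87 ± 0.18 (SE). AT3G59240 and AT2G14090 stood at 158.3 ± 2.5 and 158.3 ± 4.5 in es3dd (SD, n = 4), on different chromosomes. In limma WES1, AT1G63150 and these 3 genes had adjusted p from 6.3e-39 to 3.7e-21, and none of them changed direction with the scaling.

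Of 36 miRNA target transcripts 28 rose (31 adjusted over the list alone), median 3.00, adjusted p = 1.7e-40 and 6.35e-05 with an estimated correlation. All 5 tested PPR genes rose (5 adjusted over the list alone), median 6.10, adjusted p = 3.3e-26 and 1.7e-04 with an estimated correlation. All 3 ARF genes rose (3 adjusted over the list alone), median 2.47, adjusted p = 4.3e-05 and 0.0121 with an estimated correlation. Of 5 NLR genes 4 rose (5 adjusted over the list alone), median 2.19, adjusted p = 2.25e-09 and 0.00194 with an estimated correlation. AT5G43740 (chromosome 5, 17564697 to 17569148) stood at 287.9 ± 17.7 against 37.4 ± 6.0 (SD, n = 4). Of 9 silencing factors 4 rose (6 adjusted over the list alone), median 1.39, adjusted p = 2.1e-04 and 0.0121 with an estimated correlation. AGO1 rose by 3.12 ± 0.25 and DCL1 by 2.79 ± 0.32 log2 units (SE). Of 10 ABA, cold and drought genes 7 rose (7 adjusted over the list alone), median 1.61, adjusted p = 2.1e-05 and 0.00778 with an estimated correlation. These 6 lists kept their direction under each scaling, as did the housekeeping list, whose median fell to 0.05 when median-centred.

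Of 11 nitrogen genes 4 rose (4 adjusted over the list alone), median 0.88, without a camera call at adjusted p = 0.0524, and 2 rose when median-centred and 10 under scaling to MIR loci or plastid-encoded genes. GLT1 (AT5G53460, chromosome 5, 21700187 to 21710296), a glutamate synthase gene, stood at 123.8 ± 20.2 against 19.5 ± 5.7 (SD, n = 4). Of 5 SMAX1-LIKE genes 2 rose (4 adjusted over the list alone), median 1.3, adjusted p = 0.116, with 1 higher when median-centred and 5 under scaling to MIR loci. Of 10 housekeeping genes 1 rose (1 adjusted over the list alone), median 0.48, adjusted p = 0.228, with 0 higher and 1 lower when median-centred and 9 higher under scaling to MIR loci or plastid-encoded genes. By limma 0 of 4 decay factors were called (0 adjusted over the list alone), median -0.01, adjusted p = 0.788, with 3 higher under scaling to MIR loci. SCR rose by 2.63 ± 0.39 log2 units (SE). Of 17 photosynthesis genes 5 fell and 0 rose (5 adjusted over the list alone), median -0.74, adjusted p = 1.6e-19 and 0.00176 with an estimated correlation. When median-centred 13 fell, under housekeeping scaling 0 were called, and the median turned to 0.53 and 0.52 under scaling to MIR loci and plastid-encoded genes. Of 78 plastid-encoded genes 52 fell (54 adjusted over the list alone), median -1.24, adjusted p = 8.7e-49 and 1.7e-04 with an estimated correlation. Of 94 MIR loci 54 fell and 2 rose (61 and 4 adjusted over the list alone), median -1.28, adjusted p = 2.3e-33 and 0.00118 with an estimated correlation, but 15 lower and 16 higher when scaled to plastid-encoded genes. Under scaling to MIR loci, 2 plastid-encoded genes were lower and 4 higher. Of 112 mitochondrion-encoded genes 6 rose and 4 fell (5 and 3 adjusted over the list alone), median 0.15, adjusted p = 0.224, and the median turned to -0.28 and -0.07 under median-centring and quantile normalization. It was 1.41 and 1.40 under scaling to MIR loci and plastid-encoded genes, where 78 and 77 were higher and 0 lower. Of 58 transposable element genes 5 rose and 5 fell (5 and 5 adjusted over the list alone), median 0.01, adjusted p = 0.0963, and that median was -0.42 and -0.29 under median-centring and quantile normalization. It was 0.36 under housekeeping scaling (10 higher, 2 lower), and 1.28 and 1.27 under scaling to MIR loci and plastid-encoded genes (33 higher and 0 lower in both).

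The 22-nt median of all genes lay 0.30 log2 units higher in es3. The share of called genes that rose was 77.9% on the authors' scaling, 43.4% when median-centred (1216 higher, 1584 lower), 50.1% after quantile normalization (1227 and 1223), 93.4% with housekeeping and photosynthesis genes as the reference (3843 and 270), and 99.7% with MIR loci (10451 and 36) or plastid-encoded genes (10396 and 36). In the authors' deposited table, 1538 genes were higher and 534 lower of 14139, and SMXL5 had a log2 fold change of 11.12. GRF5 (AT3G13960, chromosome 3, 4608076 to 4610497), a growth regulator, had 847.4 as the authors' mean in es3 and 0 reads in the 4 es3dd libraries, at least 1311-fold higher against a floor of 3 reads over the group. SMXL4 had 572.2 as the authors' mean in es3 and 2 reads in the es3dd libraries, a ratio of 1291 (95% exact Poisson interval of that count 357 to 10659). All 10 PPR genes (10 adjusted over the list alone) and the 4 study genes (4 adjusted over the list alone) were higher in the authors' deposited table. NIA2 had 7.56 and NIA1 6.67 in the authors' deposited table. Among 13475 genes tested in both, limma and the authors' deposited table shared 1486 rises and 477 falls, with 0 in opposite directions.

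**Figure D3:**
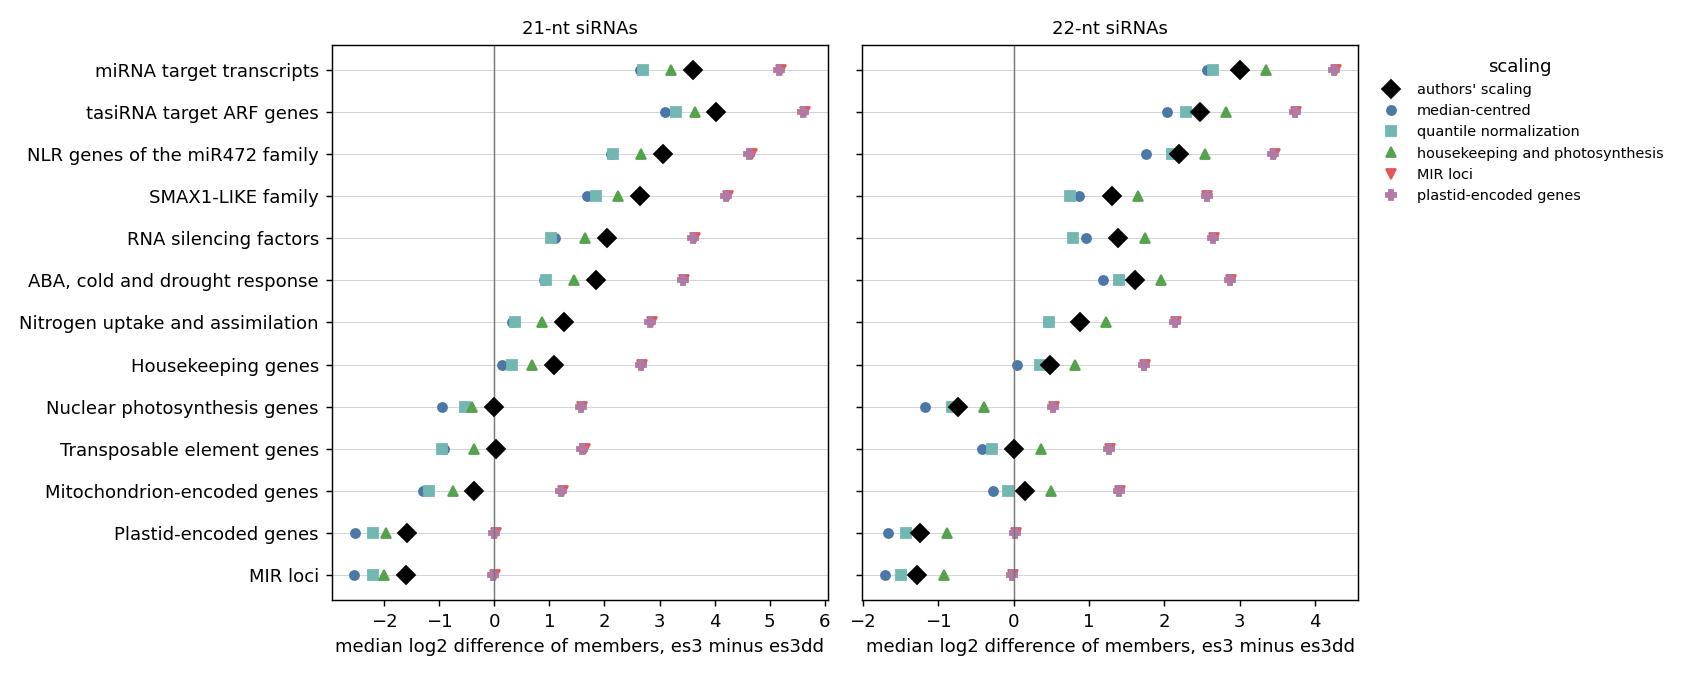
Each point is the median log2 difference (es3 minus es3dd) over the tested members of a gene list, at 21 nt and 22 nt, with 1 symbol for each of 6 scalings. Medians of miRNA targets, ARF genes, NLR genes and silencing factors stayed above 0 under all 6. So did those of SMAX1-LIKE, ABA, cold and drought, nitrogen and housekeeping genes, the last as low as 0.05 at 22 nt when median-centred. Those of photosynthesis, transposable element and mitochondrion-encoded genes lay on both sides of 0. Those of plastid-encoded genes and MIR loci lay near 0 when scaled to either list, which the scaling itself sets for the list it uses.

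The mutated genes themselves carried few siRNAs. At 21 nt, EIN5 (AT1G54490, chromosome 1, 20350109 to 20356916) stood at 3.38 ± 1.84 in es3 and 1.13 ± 0.86 in es3dd (SD, n = 4), a difference of 1 ± 0.5 (SE) in limma that did not pass the test, adjusted p = 0.084, and lay at -0.02 after quantile normalization. SKI2 (AT3G46960, chromosome 3, 17290873 to 17298222) rose by 1.74 ± 0.50, DCL2 (AT3G03300, chromosome 3, 767880 to 776214) by 1.97 ± 0.48 and DCL4 (AT5G20320, chromosome 5, 6859212 to 6869307) by 1.77 ± 0.47 log2 units (SE), with adjusted p of 0.005, 0.0013 and 0.0028 in limma, and these 3 calls were lost under median-centring and quantile normalization. At 22 nt, EIN5, SKI2 and DCL4 differed by 1 ± 0.57, 0.04 ± 0.58 and 0.61 ± 0.49 (SE), none passed the test, and the SKI2 difference changed sign under median-centring and quantile normalization.

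The ratio of 22-nt to 21-nt values asks from which genes the longer class outnumbers the shorter, relative to the scale of each class. Within es3, most called genes lay on the 21-nt side on the authors' scaling: 4908 of 21239 genes were lower and 2314 higher at 22 nt. By annotated class, 1763 of 3557 pseudogenes and 392 of 16900 protein-coding genes were higher, and 32 and 4782 were lower. MIR395b (AT1G26975, chromosome 1, 9364471 to 9364570) stood at 161.6 ± 27.8 at 21 nt and 0.40 ± 0.46 at 22 nt (SD, n = 4), a log2 ratio of -6.90 ± 0.29 (SE). In the other direction MIR156b (AT4G30972, chromosome 4, 15074899 to 15075081) stood at 27.0 ± 3.6 at 21 nt and 266.8 ± 20.4 at 22 nt (SD, n = 4), a log2 ratio of 3.26 ± 0.13 (SE). MIR845b (AT4G23375, chromosome 4, 12214069 to 12214167) had 0 reads at 21 nt and 19.5 ± 4.2 at 22 nt (SD, n = 4), at least 35-fold higher against a floor of 3 reads over the group.

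MIR395c (AT1G26985, chromosome 1, 9367080 to 9367179) and MIR395f (AT1G69797, chromosome 1, 26273858 to 26273969) had the same ratio as MIR395b to 2 decimals. The values of MIR395b and MIR395c were identical in every recovered library, and those of MIR395f nearly so. These loci are therefore not separate evidence, although each counts as a member of the MIR list. MIR390a (AT2G38325, chromosome 2, 16061954 to 16062060), which starts tasiRNA production from TAS3, had -6.74 ± 0.28 and MIR393a (AT2G39885, chromosome 2, 16652101 to 16652233) -6.23 ± 0.28 (SE). AT4G20095 (chromosome 4, 10871643 to 10873615) stood at 1.92 ± 2.82 at 21 nt and 21.4 ± 5.5 at 22 nt (SD, n = 4). By list, 64 of 100 MIR loci were lower and 12 higher at 22 nt (64 and 14 adjusted over the list alone), median -1.95, adjusted p = 9.6e-31 and 7.1e-04 with an estimated correlation. Of 26 miRNA targets 19 were lower (20 adjusted over the list alone), median -1.40, adjusted p = 2.4e-11 and 0.0183 with an estimated correlation. All 3 ARF genes, 3 NLR genes and 5 SMAX1-LIKE genes were lower (3, 3 and 5 adjusted over each list alone), with medians of -1.41, -1.59 and -1.58 and adjusted p of 1.5e-04, 0.00284 and 0.00298. With an estimated correlation these had adjusted p = 0.0193, adjusted p = 0.0419 and adjusted p = 0.0768. Of 17 silencing factors 8 were lower (8 adjusted over the list alone), median -1.13, adjusted p = 0.00418 and 0.0911 with an estimated correlation. Of 17 photosynthesis genes and 10 ABA, cold and drought genes 5 each were lower (5 and 5 adjusted over each list alone), medians -0.85 and -0.95, adjusted p = 2.4e-09 and 0.00109, and 0.0183 and 0.0419 with an estimated correlation. Of 11 housekeeping genes 2 were lower (3 adjusted over the list alone), median -0.77, adjusted p = 0.0105 and 0.0589 with an estimated correlation. Of 117 mitochondrion-encoded genes 42 were higher (44 adjusted over the list alone), median 0.85, adjusted p = 2.2e-15 and 3.0e-04 with an estimated correlation. Of 66 transposable element genes 18 were higher and 8 lower (18 and 8 adjusted over the list alone), median 0.39, adjusted p = 0.00284 and 0.101 with an estimated correlation. That list may miss other transposable element genes. Plastid-encoded genes (4 of 84 lower), decay factors (2 of 7 lower), nitrogen genes (1 of 10 lower) and root-specific genes (1 of 2 lower) had no camera call, at adjusted p of 0.442, 0.487, 0.487 and 0.141, with 3, 2, 1 and 1 lower adjusted over each list alone.

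Within es3dd, where DCL4 and DCL2 are absent, called genes were fewer and lay mostly on the 22-nt side: 767 of 16748 were higher and 170 lower, but only 123 and 101 in limma without the trend. MIR845b had 0.45 ± 0.52 at 21 nt and 47.8 ± 16.9 at 22 nt (SD, n = 4), a log2 ratio of 5.07 ± 0.40 (SE). AT2G10920 (chromosome 2, 4301708 to 4302134, uncharacterized) had 0.90 ± 1.04 and 27.5 ± 7.8, and MIR169k (AT3G26815, chromosome 3, 9875525 to 9875737) 0.91 ± 1.83 and 24.1 ± 11.4 (SD, n = 4). The lowest ratios were at MIR170 (AT5G66045, chromosome 5, 26411580 to 26411672), -7.25 ± 0.27, AT3G57710 (chromosome 3, 21384676 to 21387399), a protein kinase gene, -6.95 ± 0.23, and MIR171b (AT1G11735, chromosome 1, 3961348 to 3961464), -5.98 ± 0.28 (SE). Another MIR locus had 21-nt values close to those of MIR170 in every recovered library, so MIR170 may share its reads. Of 93 MIR loci 55 were lower and 8 higher (59 and 11 adjusted over the list alone), median -2.14, adjusted p = 5.2e-181 and 3.1e-05 with an estimated correlation. Of 79 plastid-encoded genes 11 were lower (11 adjusted over the list alone), median -0.37, adjusted p = 8.1e-28 and 0.0163 with an estimated correlation. Of 11 silencing factors 1 was lower (1 adjusted over the list alone), median -0.38, adjusted p = 6.4e-04 and 0.0365 with an estimated correlation. Of 117 mitochondrion-encoded genes 10 were higher and of 68 transposable element genes 8 (12 and 9 adjusted over each list alone), medians 0.43 and 0.30, adjusted p = 0.0341 and 0.0406, with adjusted p = 0.123 and adjusted p = 0.0809 with an estimated correlation. Of the 4 study genes 1 was lower (1 adjusted over the list alone), median -0.79, adjusted p = 0.0406 and 0.265 with an estimated correlation, and the choice of these genes by the study makes this no independent evidence. Among the other lists, 1 of 36 miRNA targets, 1 of 10 PPR genes and 1 of 8 SMAX1-LIKE genes were lower (0, 1 and 1 adjusted over each list alone), with camera adjusted p of 0.0667, 0.261 and 0.117. In limma 0 of 3 ARF genes, 4 decay factors, 4 NLR genes, 13 nitrogen genes, 17 photosynthesis genes, 9 ABA, cold and drought genes, 11 housekeeping genes and 1 root-specific gene were called, with 0 adjusted over each list alone and camera adjusted p from 0.0667 to 0.776 for those with more than 1 member. The median log2 ratio of all genes was -0.54 in es3 and 0.17 in es3dd. When it was set to 0, es3 had 3730 higher and 1858 lower (66.8% higher against 32%), and es3dd 652 and 166.

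The difference between these ratios tests whether loss of DCL4 and DCL2 changed the balance of the classes. The ratio was lower in es3 at 1509 of 20397 genes and higher at 379, but with a pseudocount of 0.1 at only 441 and 258. GH3.1 (AT2G14960, chromosome 2, 6451319 to 6453797), an auxin-conjugating enzyme gene, had 10.8 ± 1.9 at 21 nt and 0 reads at 22 nt in es3 (SD, n = 4), and 0 and 0.44 ± 0.88 in es3dd (SD, n = 4), so that es3dd gives it no measurable ratio and the size of its difference is set by the pseudocount. AGO2 (AT1G31280, chromosome 1, 11181504 to 11185396), an antiviral Argonaute gene, went the other way. It stood at 92.3 ± 12.2 in es3 and 98.9 ± 48.0 in es3dd at 21 nt, and at 14.1 ± 2.3 and 1.52 ± 1.34 at 22 nt (SD, n = 4), a difference of ratios of 2.71 ± 0.40 (SE), adjusted p = 3.6e-07.

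IBR10 (AT4G14430, chromosome 4, 8304442 to 8305857) had a difference of -3.74 ± 0.69, AT1G55210 (chromosome 1, 20597734 to 20598768), a dirigent-like gene, -3.71 ± 0.49 and GRP5 (AT3G20470, chromosome 3, 7140294 to 7141353) -3.62 ± 0.57 (SE). IBR10 stood at only 0.23 ± 0.47 at 21 nt and 2.2 ± 2.3 at 22 nt in es3dd (SD, n = 4). AT1G55210 stood at 105.5 ± 2.5 in es3 and 0.67 ± 0.85 in es3dd at 21 nt (SD, n = 4). Ratios were higher in es3 at AT4G30750 (chromosome 4, 14980853 to 14982404) by 3.77 ± 0.65 and EMB1006 (AT5G50280, chromosome 5, 20458939 to 20461710), a PPR gene, by 2.94 ± 0.69 (SE), calls that were lost with a pseudocount of 0.1. AT3G59180 (chromosome 3, 21880719 to 21882459) and MIR447c (AT4G03438, chromosome 4, 1523306 to 1523503) were also called higher, but had 0 reads at 22 nt in both genotypes, so only their 21-nt values (0.77 ± 0.63 against 13.3 ± 2.5, and 3.15 ± 1.88 against 29.7 ± 3.7, SD, n = 4) differed. Of 26 miRNA targets 10 were lower (13 adjusted over the list alone), median -1.18, adjusted p = 4.2e-04 and 0.00334 with an estimated correlation. Of 17 photosynthesis genes 4 were lower (4 adjusted over the list alone), median -0.77, adjusted p = 2.2e-13 and 0.00334 with an estimated correlation. MIR loci (15 of 91 higher and 2 lower, median 0.67), mitochondrion-encoded genes (11 of 119 higher, median 0.42) and plastid-encoded genes (4 of 79 higher and 1 lower, median 0.39) moved up relative to other genes, at adjusted p of 5e-14, 5e-14 and 7.6e-12, and 0.00113, 2e-05 and 0.00157 with an estimated correlation. Adjusted over each list alone these were 17 higher and 2 lower, 11 higher, and 4 higher and 1 lower. Among smaller lists, 2 of 3 ARF genes, 2 of 5 SMAX1-LIKE genes, 3 of 10 ABA, cold and drought genes and 0 of 11 housekeeping genes were lower (2, 3, 3 and 0 adjusted over each list alone), at camera adjusted p of 0.0318, 0.0358, 0.0318 and 0.0318, each lost at adjusted p = 0.0593 with an estimated correlation. Of 69 transposable element genes 2 were higher and 3 lower (2 and 3 adjusted over the list alone), above the other genes at adjusted p = 0.0318 and also lost at adjusted p = 0.0593 with an estimated correlation. Silencing factors (1 of 15 higher and 1 lower), decay factors (1 of 7 lower), NLR genes (0 of 3) and nitrogen genes (0 of 10) had no camera call, at adjusted p of 0.669, 0.316, 0.104 and 0.877, with 2, 1, 2 and 0 called adjusted over each list alone, and SCR was lower. The median difference of all genes was -0.52. Once it was set to 0, 2518 genes were higher and 165 lower (93.9% higher against 20.1%), and on the read scale of both classes 170 were higher and 2366 lower (6.7%), so that the split of directions depends on how the size classes are set against each other.

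The last comparison sets es3 against Col and asks which siRNAs appear when RNA decay fails. How the Col libraries were made is not given by the labels. A difference from Col in either direction therefore cannot be told apart from a difference in library preparation or processing. The authors' deposited table has 3837 genes higher and 702 lower of 18061 at 21 nt, and 1149 higher and 580 lower of 14640 at 22 nt. At 21 nt WES1 is listed at 0 in Col and had 539.1 as the authors' mean in es3. The largest other 21-nt log2 fold changes in the authors' deposited table were those of SMXL5 with 10.86, the cytokinin response factor CRF2 (AT4G23750, chromosome 4, 12376122 to 12378032) with 10.81, FMO with 10.51 and GRF5 with 10.45. At 22 nt the authors' deposited table is led by CRF2 with 10.42, the GH3 gene DFL1 (AT5G54510, chromosome 5, 22130964 to 22133688) with 9.93 and GRF5 with 9.84. FMO and GRF5 at 21 nt and CRF2, DFL1 and GRF5 at 22 nt had 0.67, 1.63, 1.26, 0.63 and 0.88 as the authors' mean in Col, near the level of single reads, so that the size of these folds is uncertain.

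NIA2 had 32.4 at 21 nt and 100.3 at 22 nt as the authors' mean in Col, and 12110 and 3343 as the authors' mean in es3. Thus the 22-nt mean exceeded the 21-nt mean at NIA2 in Col, each on the scale of its own class, with a ratio of 3.09, against 0.28 in es3. The other 3 study genes had ratios of 6.30 (NIA1), 10.9 (SMXL4) and 4.12 (SMXL5) of the authors' means in Col, and 0.39, 0.27 and 0.28 in es3. SMXL7 (AT2G29970, chromosome 2, 12776208 to 12780069), of the same family as SMXL4, had a ratio of 0.42 in Col. Against Col the authors' deposited table gives NIA2 8.55 and 5.06, NIA1 7.37 and 3.35, SMXL4 10.3 and 5.05, and SMXL5 10.86 and 6.97, at 21 and 22 nt. Other abundant es3 genes were GAE6 (AT3G23820, chromosome 3, 8603212 to 8605810), a cell wall sugar epimerase gene, and AK3 (AT3G02020, chromosome 3, 337712 to 343912), an aspartate kinase gene, with 8952 and 8308 at 21 nt as the authors' mean. ARF6 (AT1G30330, chromosome 1, 10685822 to 10690988) had 2708 in es3 and 8.14 in Col as the authors' mean.

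No PPR gene of the cluster was called against Col, with 0 of 10 in either class in the authors' deposited table (0 adjusted over the list alone). Even so, AT1G62914 (0.49, adjusted p = 4.6e-07), AT1G63080 (0.45, adjusted p = 1.8e-05) and AT1G63400 (0.44, adjusted p = 3.4e-06) were higher at 22 nt there by less than the log2 threshold. RPF2, for example, had 721.9 in Col and 752 in es3 at 21 nt as the authors' mean. Of 38 miRNA targets 32 were higher at 21 nt (33 adjusted over the list alone) and of 36 at 22 nt 27 were higher and 1 lower (31 and 1 adjusted over the list alone) in the authors' deposited table. All 8 SMAX1-LIKE genes were higher at 21 nt (8 adjusted over the list alone) and 3 of 8 at 22 nt (5 adjusted over the list alone) in the authors' deposited table. Photosynthesis genes went down, with 15 of 20 lower at 21 nt and 20 of 20 at 22 nt (15 and 20 adjusted over the list alone) in the authors' deposited table. Plastid-encoded genes did too, with 84 of 88 and 80 of 88 lower (86 and 80 adjusted over the list alone) in the authors' deposited table. All 4 study genes were higher in both classes in the authors' deposited table (4 and 4 adjusted over the list alone), which their choice by the study makes no independent evidence. The same limit holds for SMXL4 and SMXL5 within the SMAX1-LIKE family and for NIA1 and NIA2 within the nitrogen genes. Of the ARF genes 2 and 3 of 3 were higher, of silencing factors 5 of 11 and 3 of 9, of NLR genes 3 and 2 of 5, of ABA, cold and drought genes 6 of 10 and 6 of 8, at 21 and 22 nt in the authors' deposited table (2 and 3, 6 and 3, 3 and 2, 7 and 6 adjusted over each list alone). Nitrogen genes had 5 higher and 1 lower of 13, then 5 and 2 of 13, and MIR loci 10 and 49 of 138, then 9 and 19 of 114, in the authors' deposited table (6 and 1, 5 and 2, 11 and 52, 12 and 19 adjusted over each list alone). Mitochondrion-encoded genes had 0 higher and 26 lower of 111, then 1 and 5 of 116, and transposable element genes 9 and 4 of 61, then 6 and 0 of 63, in the authors' deposited table (the same counts adjusted over each list alone). Of housekeeping genes 1 of 11 and 0 of 10 were higher, of decay factors 0 of 7 and 0 of 5, and SCR was higher in both classes in the authors' deposited table (the same counts adjusted over each list alone). The gene of the large Rubisco subunit, ATCG00490, had -3.02 and -2.59 in the authors' deposited table. Falls were led by AT2G01021 (chromosome 2, 6571 to 6672), then AT5G39205 (chromosome 5, 15700770 to 15700976) at 21 nt, with 8.31 as the authors' mean in Col and 0 reads in es3, and AGL12 (AT1G71692, chromosome 1, 26952545 to 26955127) at 22 nt, with 20.3 and 0.44 as the authors' mean in Col and es3, in the authors' deposited table. The median log2 fold change was 0.74 at 21 nt and 0.19 at 22 nt over the genes of the authors' deposited table, and libraries of Col were not among the labelled samples, so no scaling other than the authors' was tried on this comparison.

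**Figure D4:**
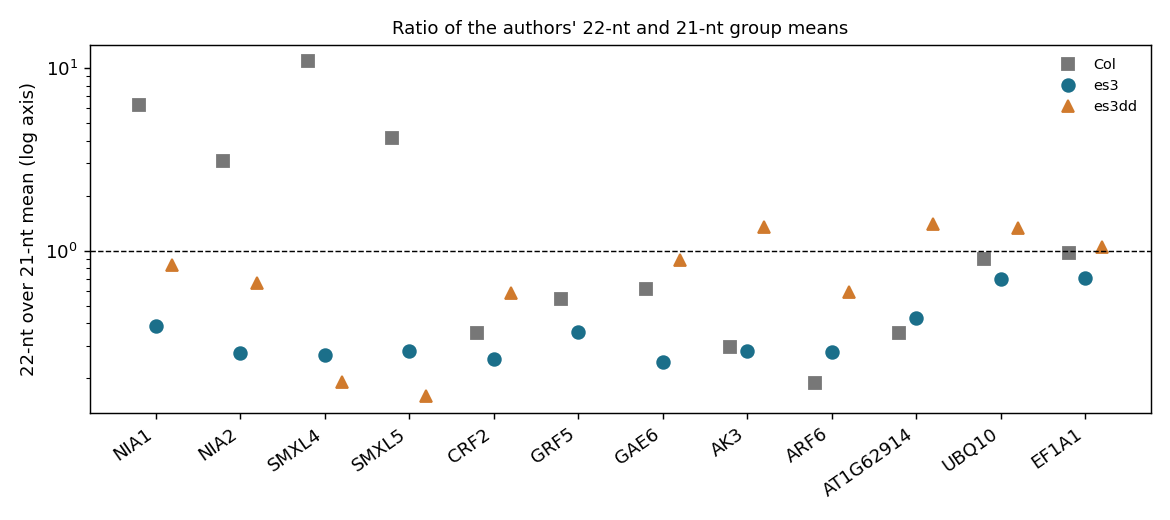
Points give the ratio of the authors' 22-nt to 21-nt group mean on a log axis for 12 genes in Col, es3 and es3dd, with a dashed line at 1 and without error bars because these are means of the authors. In Col the ratio lay above 1 at NIA1, NIA2, SMXL4 and SMXL5 (3.09 to 10.9), and in es3 it lay below 1 at all 12, while GRF5 has no es3dd point since its 22-nt mean is 0 there.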

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

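The search for single libraries far from the rest and the comparison of ratios were fixed in advance, and the test on AT2G01021 was written before its value was seen, although AT2G01021 itself was picked out after its level had been seen.

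AT2G01021 had 14317 at 21 nt and 15030 at 22 nt as the authors' mean in Col, and 0 reads in all 4 libraries of es3 and of es3dd. It drew attention as a value outside the labelled libraries. It lies at 6571 to 6672 on chromosome 2, next to an annotated 5.8S ribosomal RNA gene. A filter that removed many genes from es3 and es3dd but not from Col could leave such values, yet 0 other genes with a Col mean of 100 or more were at 0 in both. A filter on ribosomal sequence alone, or a true absence, could also give this, and the values do not tell these apart.

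The 22-nt to 21-nt ratio differed between the genotypes at 1509 genes that were lower and 379 that were higher in es3, a split that depends on how the size classes are set against each other.

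A test of the gap between the extreme library and its neighbour marked 29 of 249 groups of 4 libraries. Its chance rate of about 1 in 20 is for continuous values, and most marks were a few reads in 1 library against 0 in the others, so no excess over chance was shown. Among es3 libraries at 21 nt it marked AGL12 with 1.457 where the others had 0 and AT4G20095 with 6.115 where the others had 0 to 0.82. Among es3 libraries at 22 nt it marked AT1G63150 with 252.877 (others 275.206 to 277.537), AT3G27250 with 34.123 (61.022 to 65.255), MIR845b with 13.24 (21.232 to 22.036) and MIR169k with 2.543 (0.758 to 0.946). There MIR171b with 0.946, AGL12 with 1.775 and AT5G39205 with 0.946 had 0 in the other libraries. Among es3dd libraries at 21 nt it marked AT5G39205 with 5.584 (others 11.516 to 12.558), AT1G63150 with 2.898 (1.772 to 1.861), AT1G63400 with 0.915 (1.772 to 1.932) and SCR with 1.932 (0.886 to 0.931). There AT1G12300 with 2.744, RPF2 with 0.966, PS2 with 1.829, DCL2 with 0.966, MIR169k with 3.658, SKI2 with 0.931, IBR10 with 0.931, WES1 with 2.658 and UF3GT with 1.829 had 0 in the other libraries. Among es3dd libraries at 22 nt FMO with 0.876, AGO7 with 0.884, AGL12 with 0.884, GH3.1 with 1.768, DCL2 with 0.805 and EMB1006 with 0.884 had 0 in the others. The scale of the es3dd 22-nt libraries was marked too, with 1 library at 1.243 (in units of 1e6 reads) and the others at 1.125 to 1.142.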

How the results depend on the processing

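Scaling to MIR loci, scaling to plastid-encoded genes, the read scale of both size classes and the minimum of 10 in the authors' table were chosen after results had been seen. The cause of each change below was not tested. At 21 nt, 7926 genes were higher and 1317 lower in es3 than in es3dd, and this became 3217 and 429 with a pseudocount of 5, 1505 and 513 for genes with a mean of at least 10, 3272 and 4345 when median-centred, 3243 and 4342 after quantile normalization, 5653 and 2591 on housekeeping and photosynthesis genes, 14374 and 43 on MIR loci, and 14242 and 47 on plastid-encoded genes. At 22 nt, 2200 and 624 became, in the same order, 856 and 225, 464 and 282, 1216 and 1584, 1227 and 1223, 3843 and 270, 10451 and 36, and 10396 and 36. Within es3, 2314 higher and 4908 lower at 22 nt became 1124 and 1672 with a pseudocount of 5, 1816 and 2793 for genes with a mean of at least 10, and 3730 and 1858 when median-centred. Within es3dd, 767 and 170 became 308 and 109 with a pseudocount of 5, and 123 and 101 in limma without the trend. The difference of ratios, 379 and 1509, became 258 and 441 with a pseudocount of 0.1, 123 and 1058 without the trend, 2518 and 165 when median-centred, and 170 and 2366 on the read scale. Leaving out 1 library gave 6958 to 7640 higher and 1188 to 1293 lower at 21 nt, 1829 to 2000 and 532 to 595 at 22 nt, 2152 to 2241 and 4217 to 4641 within es3, 647 to 788 and 152 to 165 within es3dd, and 312 to 374 and 1111 to 1446 for the difference. Among genes with a mean of at least 10 in the authors' deposited table, es3 against es3dd had 1620 higher and 626 lower at 21 nt and 505 and 322 at 22 nt, and es3 against Col 1486 and 394, then 414 and 352. Without organelle genes, TAS and MIR loci, the authors' means summed to 344959 and 198434 in es3 and to 113728 and 137632 in es3dd, at 21 and 22 nt, and the 10 leading genes without TAS and MIR loci held 18.8% and 11.4%, and 13% and 8.9%. Genes at 1 or more in all libraries numbered 12260 and 8516 in es3 and 5702 and 6369 in es3dd, those at 100 or more 344 and 198, and 155 and 150, and 2666 genes were at 10 or more in at least 2 of 4 es3dd libraries at 21 nt. With an estimated correlation, camera called 4 lists in place of 12 at 21 nt, 7 in place of 11 within es3, 3 in place of 6 within es3dd and 5 in place of 10 for the difference. Leaving out 1 library gave 3 to 7 lists within es3dd and 6 to 10 for the difference. Among 254 results of named genes, 4475 alternatives gave 4268 the same, 130 weaker, 71 stronger and 6 reversed, and among 74 results of gene lists 880 gave 822, 46, 12 and 0. A reversal here is a gene named in the text that limma called and that took the other sign in an alternative, so genes that were not called, not named or not recovered were not counted even where their sign depends on the scaling. The 6 reversals were at MIR156b at 21 nt (0.31 on MIR loci and 0.27 on plastid-encoded genes), MIR170 at 21 nt (0.38 and 0.35) and MIR845b at 22 nt (0.06 and 0.05). A replicate block, a paired ratio within libraries, the top 10 genes of each library, totals leaving libraries out and count-based tools were planned but not run.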

Other observations

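The comparison of pseudogenes with protein-coding genes, the counts over other splits of the libraries, the test of the MIR median after scaling and the test of the lowest of the 4 Col ratios were chosen only after the results had been seen.

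Genes that the reference annotation classes as pseudogenes were called lower in es3 more often than protein-coding genes on the authors' scaling, and the counts depended on the scaling. Whether this class includes transposable element genes was not examined. Transcribed pseudogenes are a separate class there, with 69 of 317 lower and 33 higher at 21 nt on the authors' scaling. At 21 nt on the authors' scaling, 789 of 3283 pseudogenes (24%) were lower in es3 than in es3dd against 290 of 13378 protein-coding genes (2.2%), an odds ratio of 14.3 (95% interval 12.4 to 16.4). Pseudogenes had 18 higher and 2754 lower when median-centred, but 1401 and 3 when scaled to MIR loci and 1314 and 6 when scaled to plastid-encoded genes, where 0.1% to 0.2% of both kinds of gene were lower. Their median log2 difference was -0.68 against 1.33 for protein-coding genes, and 0.92 against 2.93 when scaled to MIR loci. That gap stays the same by construction, since this scaling shifts all log2 values of a library alike after the pseudocount. At 22 nt, 277 of 3487 (7.9%) were lower against 196 of 10438 (1.9%), odds ratio 4.5 (3.7 to 5.4), Fisher exact p = 6.3e-56, but pseudogenes had 5 higher and 820 lower when median-centred, 162 and 92 under housekeeping scaling and 1790 and 3 under scaling to MIR loci. Within es3, 1763 of 3557 pseudogenes (49.6%) were higher at 22 nt than at 21 nt against 392 of 16900 protein-coding genes (2.3%), odds ratio 41.4 (36.7 to 46.7), and 2646 and 783 when median-centred. Genes are not independent replicates, so these intervals describe the genes of these libraries only.

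MIR loci fell in es3 at 21 nt on the authors' scaling. If siRNAs from many transcripts fill the es3 libraries, other small RNAs may take a smaller share without any change in their amount. A single factor is not the cause at every locus, since 19 of the decoded MIR loci were still lower after scaling to plastid-encoded genes, with 14 higher (39.3% called). Mitochondrion-encoded genes then had 61 of 103 higher and 0 lower, and transposable element genes a median of 1.60. The scaling followed the pseudocount, which shrinks the differences of low values. Genes called higher therefore cannot show whether they moved by that factor. The MIR median moved to -0.03 under that scaling, but over loci that went both ways this leaves open whether a factor shared with plastid-encoded genes lay behind the shift of the list. MIR loci above reach were left out of these tests. With them, the authors' deposited table gives MIR loci a median log2 fold change of -1.95 and plastid-encoded genes -1.62. The 10 leading es3 genes outside MIR loci could not account for the fall of the decoded MIR loci, as they held 6.6% of the total to which the values were scaled, a share that moves the median only from -1.6 to -1.5 when taken out.

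At NIA1, NIA2, SMXL4 and SMXL5 the authors' mean was higher at 22 nt than at 21 nt in Col and lower in es3, on values scaled apart by size class that do not count siRNAs across the classes. Reads carried over from es3 libraries could give low Col values, and over 141 genes specific to es3 the median log2 ratio in Col lay 1 above that in es3 (interval 0.91 to 1.26), which leaves some carry-over undecided. Carry-over as the whole of these values would give the es3 ratio, but the lowest of the 4 genes lay 3.49 above it. Scaling of the size classes could not explain the whole of the difference at the 4 genes, with a median shift of -0.2 over 1503 genes against 3.95. Over genes whose 21-nt and 22-nt means summed to at least 1, the median log2 ratio was 0.02 in Col and -0.53 in es3, the other direction. Of the 141 genes specific to es3, 128 had a higher ratio in Col, so that direction was not particular to the 4 genes. A shift towards 22-nt siRNAs at these transcripts in Col, relative to other genes, remains possible, and the study chose these genes for their 22-nt siRNAs.

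Other splits of the libraries were used to ask whether chance could give as many called genes. At 21 nt the real split called 9243 genes and the highest other 0, and at 22 nt 2824 and 0, so that 1 of 35 splits was as large in each. Within es3 the real split called 7222 and the highest other 9, and within es3dd 937 and 90, again 1 of 35 each. The real split is counted here, so 1 of 35 is the lowest share possible. Every other split mixes the groups compared, which puts a real difference into its spread. Low counts there are therefore no measure of chance. For the difference of ratios the real split called 1888 and the highest other 4949, and 3 of 100 splits were as large. A split can part the genotypes in 1 size class and mix them in the other, and it could then carry the genotype difference of that class. Which splits gave the larger counts was not examined, so whether this lay behind them was not tested.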
